A study of Mus musculus with 11 samples.

How the data were processed

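Heart tissue RNA from 11 mouse libraries was measured by strand-specific sequencing after removal of ribosomal RNA, from 400 ng of total RNA per library. The libraries form 4 groups by their labels: Control (2), endothelial Cd36 knockout through Tie2-cre (3, EC KO), cardiomyocyte Cd36 knockout through MHC-cre (3, CM KO) and total Cd36 knockout (3, Total KO). The labels give the Control group no Cre and do not state how the total knockout was made. Each library has a number of its own in its label, and the labels do not say what the numbers stand for, so p-values measure the spread between these libraries. Replicate numbers follow the order of deposit. No paired analysis was possible because no label links a library of one group to a library of another. The label numbers fall in separate runs for CM KO, for EC KO together with Control, and for Total KO.

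Per the submitters' processing notes, reads were handled with TopHat2 (version not given), HTSeq 0.8.0 and DESeq2 (given as version 3.5) on the mm10 build; the notes do not state the counting mode, strand setting, annotation or filters. The deposited signal values are counts of whole reads per gene that the authors divided by one factor per library. Each of the 257620 values lay within 0.05 reads of a whole multiple of its library's smallest step, so whole reads were recovered by dividing by that step. The table held 23420 genes and no column of sample values was left unused. Of these genes, 4716 stood at 0 in every library, 27 carried a date in place of a symbol and 2 symbols were repeated. Genes encoded by mitochondrial DNA were not in the table.

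Recovered reads per library were 17058598 and 18258252 in Control, 2268403, 16560642 and 15609595 in EC KO, 15582950, 20105673 and 15848956 in CM KO, and 11157062, 15974962 and 16753994 in Total KO, and 14031 to 16755 genes were above 0. Between libraries of one group, the chi-square of the counts per degree of freedom ranged from 2.93 to 59.4 and Pearson's r across genes from 0.970 to 0.992. The chi-square of 2.93 was that of EC KO replicates 1 and 2, a pair that holds the library with the fewest reads. The 2 Control libraries (28.5, r = 0.983) were no closer to each other than to some knockout libraries. Total KO replicate 3 stood at 24.2 (r = 0.984) from Control replicate 1 and at 16.4 (r = 0.987) from Control replicate 2.

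Values were taken as log2 of the value plus 1 for the 12976 genes with a mean of at least 10. One limma model (3.58.1, R 4.3.3) with a trended prior variance was fitted to all 11 libraries, with 6 contrasts between the 4 groups and an F test over the 3 contrasts against Control. P-values were adjusted by Benjamini-Hochberg within each contrast and called under 0.05. Gene lists for metabolism, stress, signalling and cell type markers (35 fixed before the data were examined, 32 tested) were tested by limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison. List tests were repeated with camera's estimated correlation, under which 0 of the 67 calls held, and with fry, which asks whether a list's genes move, on balance, one way. The mixed form of fry asks whether they move in either direction. Counts of list members are given over all genes and adjusted over the list alone.

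The design, lists, alternatives and the rule for named genes were set before the data were examined. The rule names, per comparison, Cd36, the 10 genes with the largest rise and the 10 with the largest fall among those that passed, with a mean of at least 50 in the higher group and ranges that do not overlap (chance gives 10% of genes for 3 against 3 libraries and 20% for 3 against 2). It passes over predicted genes, and adds the members of a list that passed, the 4 members of lowest p of each list, the 10 genes of lowest p where fewer than 10 passed, and 11 genes fixed by name: Pdk4, Angptl4, Ucp3, Slc2a1, Slc2a4, Fabp3, Lpl, Plin2, Nppa, Nppb and Myh7. A gene named for one comparison may be given in others. Genes named outside the rule are marked as chosen after their values were seen. The results of some genes that the rule names are not reported here.

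The alternatives were pseudocounts of 0.5 and 5, no filter and a filter at 50, upper-quartile, quantile and library-total rescaling, a fit to the 2 groups compared, a weight per library (arrayWeights), a robust prior, edgeR 4.0.16 (quasi-likelihood with TMM factors) and DESeq2 1.42.0 on recovered reads, and each library left out in turn. Leaving out one Control library leaves a lone one, which is assumed to vary like the other groups. Leaving out EC KO, CM KO and Total KO replicates 1 together, the 3 doubted libraries, was added after the values were seen.

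The steps were tested on simulated data of 12976 genes, in which 100 differed by 1 and 100 by 2 on the log2 scale in each comparison with Control. Between EC KO and CM KO, Total KO and EC KO, and Total KO and CM KO, 199, 200 and 200 differed by 1 and 197, 200 and 195 by 2. For the comparisons with Control, limma recovered 66% to 78% of genes changed by 1 and 90% to 96% of those changed by 2, and 2.33% to 3.70% of its calls were of unchanged genes. For the comparisons between knockout groups, in the same order, it recovered 77.9%, 81.5% and 79.5% at 1 and 95.9%, 91.5% and 96.4% at 2. The share of calls of unchanged genes reached 8.11% for edgeR and 14.6% for DESeq2. A list raised in the simulation was called and 0 of 20 random lists were (camera on limma values). The genes were drawn independently, so the simulation could not show false list calls that come from correlation between genes. Overlaps between the comparisons with Control were set beside 100 simulations that share the controls and hold no change. The position of Cd36 and of other genes was taken from GENCODE vM21. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.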

Results

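Heart RNA was compared between 2 Control libraries and 3 libraries from each of 3 groups of Cd36-deficient mice. Cd36 encodes a fatty acid transporter of the plasma membrane. By the labels, it was deleted in endothelial cells through Tie2-cre (EC KO) and in cardiomyocytes through MHC-cre (CM KO). The last group was labelled as a total knockout (Total KO), with no statement of how it was made. The values sum all cell types of the heart, so they do not show in which cells Tie2-cre or MHC-cre acted. The design addresses the effect of endothelial Cd36 on lipid and glucose metabolism. Values are normalized read counts given as mean ± SD with n = 2 for Control and n = 3 for each knockout group unless stated, and differences are log2 with SE from limma.

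Cd36 averaged 39977 ± 6438 in Control, 27957 ± 2278 in EC KO (69.9% of Control), 19589 ± 3290 in CM KO (49.0%) and 21188 ± 2303 in Total KO (53.0%). The Control libraries read 44530 and 35425, above each of the 9 knockout libraries, which lay between 15792 and 30308. Cd36 fell by 1.03 ± 0.17 in CM KO against Control (limma, adjusted p = 0.00863) and was higher by 0.52 ± 0.15 in EC KO than in CM KO (limma, adjusted p = 0.0298). The differences from Control of -0.51 ± 0.17 in EC KO (limma, adjusted p = 0.298) and -0.91 ± 0.17 in Total KO (adjusted p = 0.0809) did not pass, nor did Total KO minus EC KO (-0.40 ± 0.15, adjusted p = 0.393) or minus CM KO (0.12 ± 0.15, adjusted p = 0.638). The fall in CM KO was -0.87 and no longer passed without Control replicate 1, and the fall in Total KO (-0.91) passed without CM KO replicate 1. EC KO minus CM KO no longer passed without EC KO replicate 1 (0.46), EC KO replicate 2 (0.53) or CM KO replicate 1 (0.38). Total KO minus CM KO was -0.03 without CM KO replicate 1. Each value sums the reads of all exons in all cell types of the heart, so it shows neither the deleted exon nor the protein, and a knockout group labelled total kept 53.0% of the Control value.

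**Figure D1:**
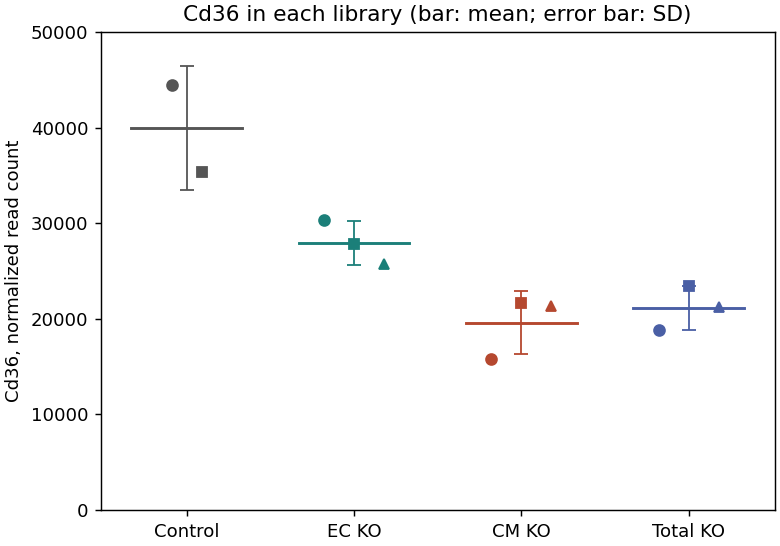
Cd36 in the 11 heart libraries: the vertical axis gives the normalized read count, each point is a library, bars are group means and error bars are SD (n = 2 for Control, n = 3 for each knockout group). The group means are 39977 in Control, 27957 in EC KO, 19589 in CM KO and 21188 in Total KO.

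Among the 4 groups, 1853 of 12976 tested genes differed (limma F test over the 3 contrasts against Control, adjusted p under 0.05). CM KO stood apart: 346 genes were higher and 224 lower in it than in each of Control, EC KO and Total KO. On the first principal component (42.3% of the variance) the CM KO libraries lay at 58.9, 24.3 and 32.3, and the other 8 between -40.4 and 1.81. EC KO replicate 1, the library with the fewest reads (2268403), lay at -40.4 on this component and at 46.3 on the second (17.7%). The F test count was 1016 without CM KO replicate 1, 940 without CM KO replicate 3 and 1142 without Total KO replicate 3.

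**Figure D2:**
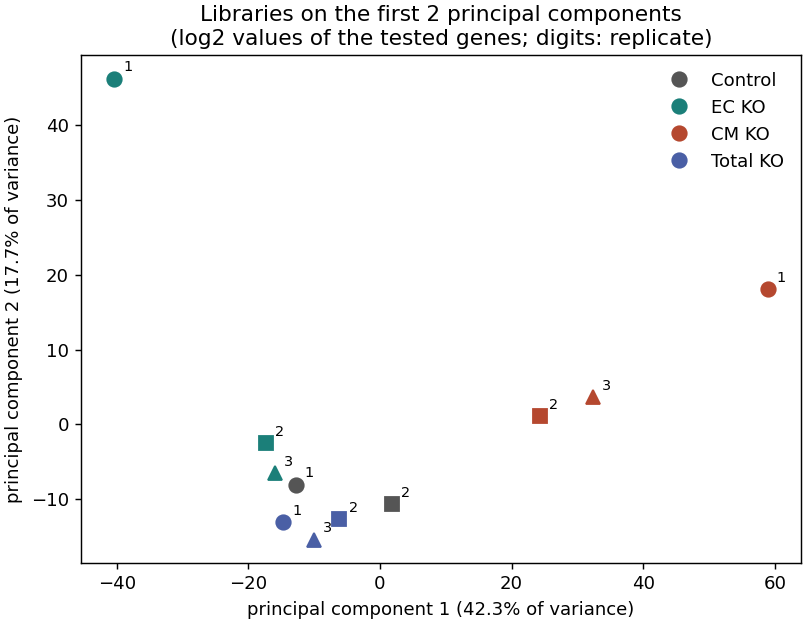
First (42.3% of the variance) and second (17.7%) principal components of the log2 values of the tested genes in the 11 heart libraries, each point a library marked by group and replicate. The 3 CM KO libraries lie at 58.9, 24.3 and 32.3 on the first component, and EC KO replicate 1 lies at 46.3 on the second.

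Deletion of Cd36 through Tie2-cre was accompanied by a rise of Syt12, of the synaptotagmin family of vesicle proteins, from 94.1 ± 19.8 in Control to 352 ± 46.0 in EC KO (log2 1.90 ± 0.19; limma, adjusted p = 0.00232). Fkbp5, a cochaperone of the glucocorticoid receptor that glucocorticoids induce, rose from 848 ± 45.5 to 2111 ± 119 (1.31 ± 0.14, adjusted p = 0.00232). Herpud1, a component of endoplasmic reticulum-associated degradation, rose from 4788 ± 1164 to 11010 ± 2015 (1.21 ± 0.17; limma, adjusted p = 0.0142). Fbp2, the muscle form of fructose bisphosphatase, fell from 793 ± 47.1 to 261 ± 48.3 (-1.62 ± 0.24; limma, adjusted p = 0.0153). Syt12 and Fkbp5 passed with each of the 11 libraries left out in turn. Herpud1 did not pass without Control replicate 2 (0.95) or EC KO replicates 1 (1.14) and 2 (1.11). Fbp2 did not pass without Control replicates 1 (-1.68) and 2 (-1.55) or EC KO replicate 2 (-1.59).

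Of the 41 genes that passed between EC KO and Control, 22 were higher and 19 lower (limma, adjusted p under 0.05; 1356 genes had an unadjusted p under 0.05). Further rises were Kcnc1, a voltage-gated potassium channel subunit (1.90), Cdo1, which oxidizes cysteine (1.72), Krt80, a keratin (1.51), the interferon-inducible guanylate-binding protein gene Gbp6 (1.30), Cnksr1, a scaffold of Ras signalling (1.14), Pdzd3 (from 47.3 ± 4.62 to 96.2 ± 15.0) and Baiap2, an adaptor of actin signalling (from 160 ± 1.75 to 321 ± 32.4). Further falls were Tnfrsf19, of the tumor necrosis factor receptor family (-1.83), the growth factor gene Fgf16 (-1.40), the adrenergic receptor gene Adra1b (from 647 ± 1.82 to 290 ± 21.8, -1.16), Rnf207 (from 1581 ± 56.8 to 722 ± 65.0, -1.13), Asb4 (-1.12), Igdcc4 (-1.05), the transcription factor gene Myc (-0.97) and Slc40a1, which encodes the iron exporter ferroportin (-0.96). The count was 5 without Control replicate 2, 12 without EC KO replicate 1 and 7 without EC KO replicate 2. It was 84 without CM KO replicate 1, 27 and 22 without CM KO replicates 2 and 3, and 26 and 25 without Total KO replicates 2 and 3. Of the 21 genes named for this comparison that passed, 9 and 2 passed without Control replicates 1 and 2, and 8, 3 and 13 without EC KO replicates 1, 2 and 3. It was 21, 15 and 14 without CM KO replicates 1, 2 and 3, and 20, 14 and 15 without Total KO replicates 1, 2 and 3. The count of 41 was 22 with no filter on low values, 27 with a weight per library, 162 by DESeq2 and 64 with 3 doubted libraries left out, and rescaling by library totals gave 15 higher and 23 lower genes.

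Camera called 7 of 32 gene lists between EC KO and Control, and 0 with an estimated correlation, while fry called 0 of 32. The mixed form of fry called 9, with the lowest adjusted p (3.05e-06) for triglyceride storage and lipolysis. In that list 1 of 25 rose over all genes, and 3 were higher and 3 lower when adjusted over the list alone. PPAR target genes were lower as a set in EC KO than in Control, with a median log2 difference of -0.31 (camera on limma values, adjusted p = 1.68e-06). With an estimated correlation, camera gave adjusted p = 0.855. Of 31 tested members, 1 fell over all genes and 3 when adjusted over the list alone. The thioesterase gene Acot2 stood at 1335 ± 79.8 against 2865 ± 67.1 (-1.10) and Cidea, of lipid droplets, at -0.57. Acot2 passed without CM KO replicate 1 or Total KO replicate 1 (-1.10 in each). Genes of mitochondrial beta-oxidation had a median of -0.22 over 25 members, of which 0 passed by limma (6 at an unadjusted p under 0.05, 0 by edgeR, 0 by DESeq2) and 0 when adjusted over the list alone. That list was called by camera (adjusted p = 0.00101), with adjusted p = 0.916 with an estimated correlation and 0.0559 without Control replicate 1. Endothelial markers were higher as a set (median 0.19 over 24; camera, adjusted p = 2.03e-04). The estimated correlation gave adjusted p = 0.253 for camera. Of its genes, 0 passed by limma over all genes (10 at an unadjusted p under 0.05, 0 by edgeR and 1 by DESeq2), with 4 higher when adjusted over the list alone. Their values included 0.36 for Robo4 and 0.32 for the adhesion molecule gene Pecam1.

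Glucocorticoid and fasting responsive genes were higher as a set in EC KO than in Control (1 of 20 rose, 7 higher when adjusted over the list alone, median 0.22; camera, adjusted p = 0.00534). Camera gave adjusted p = 0.253 with an estimated correlation. At the preset correlation the adjusted p was 0.0689 without Control replicate 2 and 0.116 with 3 doubted libraries left out. Beside Fkbp5, the cell cycle inhibitor gene Cdkn1a stood at 3125 ± 304 against 1355 ± 120 and the lipocalin gene Lcn2 at 1.53. Lcn2 and Atf4 passed without CM KO replicate 1 (1.53 and 0.50). In the same comparison, clock genes had a median of 0.58 over 4 that peak with Arntl and of -0.45 over 10 that peak with Dbp, subsets chosen after values were seen. By limma 0 of all 18 clock genes passed (8 at an unadjusted p under 0.05, 0 by edgeR and 0 by DESeq2), with 0 when adjusted over the list alone. The clock list was not called by camera (adjusted p = 0.886), which asks for a shift one way and cannot show 2 sides that move apart. The mixed form of fry gave adjusted p = 0.230 for it. Genes of the integrated stress and unfolded protein responses had a median of 0.14 over 25 members, 1 higher over all genes (Herpud1) and 4 higher when adjusted over the list alone, among them Atf4, the transcription factor of the integrated stress response, at 0.50. Camera called that list (adjusted p = 0.0323; adjusted p = 0.855 with an estimated correlation), but not without Control replicate 1 (0.146), EC KO replicate 2 (0.0632), EC KO replicate 3 (0.113) or CM KO replicate 1 (0.0521). Immediate early genes were lower as a set (1 of 23 fell, Myc, and 1 lower when adjusted over the list alone, median -0.36; camera, adjusted p = 0.00534). Under an estimated correlation, camera gave adjusted p = 0.855. The preset correlation gave an adjusted p of 0.0962 without Control replicate 2 and 0.0686 without EC KO replicate 3. Cell cycle genes were higher as a set (median 0.65 over 17; camera, adjusted p = 9.64e-06). Camera's estimated correlation gave adjusted p = 0.469. By limma 0 of its genes passed (4 at an unadjusted p under 0.05, 0 by edgeR and 0 by DESeq2), with 1 higher when adjusted over the list alone. Rrm2 stood at 0.81 and Ccna2 at 1.40.

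Genes chosen in advance for fatty acid and glucose handling and for cardiac stress had these log2 differences between EC KO and Control, none of which passed limma's test. They were -0.99 for Pdk4, an inhibitory kinase of pyruvate dehydrogenase, -0.97 for Angptl4, an inhibitor of lipoprotein lipase, -1.24 for the uncoupling protein gene Ucp3, 0.48 for Slc2a1 and 0.33 for Slc2a4, both glucose transporters. Further values were -0.19 for the fatty acid-binding protein gene Fabp3, 0.29 for lipoprotein lipase (Lpl), -0.14 for the lipid droplet gene Plin2, -0.24 for Nppa and -0.78 for Nppb, natriuretic peptides, and 0.51 for Myh7, the slow myosin heavy chain. Pdk4 stood at 37865 ± 12974 against 72548 ± 8770, and Ucp3 at 1165 ± 510 against 2537 ± 117. Nppa was 0.14 without Control replicate 2. The list of glucose uptake and glycolysis had a median of 0.04 over 25 members and was not called (camera, adjusted p = 0.167), nor was fatty acid uptake and trafficking (median -0.06 over 21, adjusted p = 0.361).

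Cardiomyocyte deletion of Cd36 was accompanied by a rise of Nppa, a natriuretic peptide, from 8115 ± 2938 in Control to 146172 ± 60498 in CM KO (log2 4.14 ± 0.38; limma, adjusted p = 0.00109), and of Myh7, the slow myosin heavy chain, from 12326 ± 2607 to 60536 ± 18998 (2.27 ± 0.38, adjusted p = 0.00971). Timp1, an inhibitor of matrix metalloproteinases, rose from 24.9 ± 14.3 to 361 ± 196 (3.79 ± 0.43; limma, adjusted p = 0.00140). Acsm5, an acyl-CoA synthetase of medium chains, fell from 205 ± 50.2 to 20.6 ± 10.7 (-3.40 ± 0.39; limma, adjusted p = 0.00140). Nppa, Timp1 (3.20 and 4.39 without Control replicates 1 and 2) and Acsm5 passed with each library left out in turn, while Myh7 (2.48) did not pass without Control replicate 1.

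Of the 739 genes that passed between CM KO and Control, 427 were higher and 312 lower (limma, adjusted p under 0.05; 2729 genes had an unadjusted p under 0.05). Further rises included Mybphl, a myosin-binding protein gene (4.57), and the matrix or secreted protein genes Cilp (4.44), Comp (4.13), Ltbp2 (4.07), Angptl7 (3.85), Postn (3.54), Col8a2 (3.39) and Tnc (3.16). Without Control replicate 1, none of these 8 genes passed, and they stood at 3.12, 3.50, 4.73, 3.47, 4.18, 3.40, 3.74 and 3.23 in this order. Postn, which encodes periostin, averaged 10189 ± 11980 against 545 ± 74.4, with CM KO libraries at 24012, 2830 and 3723. Without CM KO replicate 1, Cilp was 3.63, Comp 3.06, Ltbp2 3.14, Angptl7 3.08, Postn 2.58 and Tnc 2.81, Col8a2 fell below the filter, and all but Tnc of those tested passed. Without CM KO replicate 2, Comp was 4.93, Angptl7 4.54 and Col8a2 4.04. Without Control replicate 2, Mybphl was 6.02, Cilp 5.37, Comp 3.53 and Ltbp2 4.68. Further large falls included Cyp4f15, of the cytochrome P450 family (-3.95), the water channel gene Aqp4 (-3.69), Cox6b2, a subunit of cytochrome c oxidase (-2.51), Rhd (-2.44), the chloride channel gene Clcn1 (-2.31), Tmem150c (-2.29), Pfkfb1, which controls fructose bisphosphate levels (-2.19), and the cytokine gene Il15 (-1.99). Without CM KO replicate 1, Cyp4f15 was -3.08 (-4.54 without CM KO replicate 3), Clcn1 -1.57 and Tmem150c -1.63. Without Control replicates 1 and 2, Aqp4 was -2.94 and -4.43, Cox6b2 -1.88 and -3.14, and Rhd -1.63 and -3.25. Fbp2 and Slc40a1 were lower (-1.12 and -1.52) and Syt12 and Fkbp5 higher (1.08 and 1.09) in CM KO also. The count was 26 without Control replicate 1, 366 without CM KO replicate 1 and 476 without Total KO replicate 3. Of the 80 genes named for this comparison that passed (79 tested without Control replicate 1 or CM KO replicate 1), 6 and 55 passed without Control replicates 1 and 2, and 60, 76 and 66 without CM KO replicates 1, 2 and 3. It was 75, 69 and 74 without EC KO replicates 1, 2 and 3, and 72, 67 and 66 without Total KO replicates 1, 2 and 3. The count of 739 was 61 from a fit to these 2 groups alone and 1276 by DESeq2, and rescaling by library totals gave 568 higher and 237 lower genes.

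Camera called 18 of 32 gene lists between CM KO and Control, and 0 with an estimated correlation, while fry called 18 of 32. Genes of fibrosis and extracellular matrix were higher as a set in CM KO: 18 of 23 rose over all genes and 23 were higher when adjusted over the list alone (median 1.80; camera, adjusted p = 1.07e-16). Camera with an estimated correlation gave adjusted p = 0.226. They included the collagen genes Col1a1 (762 to 2941, 1.80) and Col3a1 (2054 to 12354, 2.29; 1.66 without CM KO replicate 1) and fibronectin (Fn1, 1.28). Macrophage and monocyte markers were higher as a set (12 of 17 rose, 15 higher when adjusted over the list alone, median 1.19; camera, adjusted p = 7.33e-14). With an estimated correlation, camera gave adjusted p = 0.226. Among its members were the lysosomal protein gene Cd68 (103 to 299), the complement gene C1qa (1.39), the growth factor receptor gene Csf1r (1.09) and the chemokine receptor gene Ccr2 (1.30). Fibroblast markers were higher as a set (7 of 15 rose, 11 higher when adjusted over the list alone, median 0.79; camera, adjusted p = 1.73e-09). The estimated correlation gave adjusted p = 0.226 for camera. The members included Pi16 (1.73), Mfap5 (2.22) and Cd248 (1.37). In inflammatory and NF-kappaB genes, 2 of 15 rose (Lcn2, 2.78, and the cytokine signalling inhibitor Socs3, 1.14), also 2 when adjusted over the list alone (median 0.43; camera, adjusted p = 6.00e-04). Camera gave adjusted p = 0.226 with an estimated correlation. Endothelial markers had a median of -0.17 over 24 members, with 0 passing by limma over all genes (4 at an unadjusted p under 0.05, 0 by edgeR and 0 by DESeq2) and 0 when adjusted over the list alone. Camera called them lower (adjusted p = 0.00947). Under an estimated correlation, camera gave adjusted p = 0.226. With the preset correlation the adjusted p was 0.0655 without CM KO replicate 3 and 0.0725 after quantile normalization.

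Genes of cardiac stress and hypertrophy were higher as a set in CM KO (8 of 20 rose; 10 higher and 1 lower when adjusted over the list alone, median 0.70; camera, adjusted p = 2.49e-06). Camera's estimated correlation gave adjusted p = 0.226. Beside Nppa and Myh7, they included Ankrd1, a sarcomeric stress-responsive gene (30422 to 104597, 1.86), and skeletal alpha-actin (Acta1, 2997 to 10813, 1.88). Nppb stood at 0.54. Atrial markers were called higher (4 of 10 rose, and 4 higher and 1 lower when adjusted over the list alone, median 0.21; camera, adjusted p = 0.0417). Camera with an estimated correlation gave adjusted p = 0.243. The 4 were Nppa, Dkk3 (2.24, and 1.58 without CM KO replicate 1), Clu (0.68) and Pam (0.54). Myl4, a myosin light chain of atrial muscle chosen after its values were seen, stood at 30.4 against 33.0 (-0.04) and at 0.42 without Control replicate 1 and 0.00 without CM KO replicate 2. That call was lost without Control replicate 1 (adjusted p = 0.108), EC KO replicates 1 (0.0763), 2 (0.0543) and 3 (0.0508) and Total KO replicate 1 (0.0538). It was also lost with no filter (0.101), upper-quartile (0.0506), quantile (0.0588) or library-total (0.107) rescaling, the 2 groups alone (0.114), a weight per library (0.0563) and 3 doubted libraries left out (0.141). Cardiomyocyte markers had a median of -0.28 over 24 members, with 0 passing by limma over all genes (4 at an unadjusted p under 0.05, 0 by edgeR and 3 by DESeq2) and 0 when adjusted over the list alone, and were called lower (camera, adjusted p = 0.00241). With an estimated correlation, camera gave adjusted p = 0.542. At the preset correlation the adjusted p was 0.0972 without Control replicate 2 and 0.380 after quantile normalization, and fry gave adjusted p = 0.205.

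Genes of mitochondrial beta-oxidation were lower as a set in CM KO: 17 of 25 fell over all genes and 23 were lower when adjusted over the list alone (median -0.63; camera, adjusted p = 1.07e-16). The estimated correlation gave adjusted p = 0.226 for camera. Eci1, an enoyl-CoA isomerase, fell from 5496 to 2607 (-1.10), Cpt2, a carnitine palmitoyltransferase, from 6076 to 3563 (-0.78), and the dehydrogenase genes Acadvl by 0.84 and Hadh by 0.94. PPAR target genes were lower as a set (12 of 31 fell and 1 rose; 19 lower and 1 higher when adjusted over the list alone, median -0.59; camera, adjusted p = 2.66e-09). Camera gave adjusted p = 0.226 with an estimated correlation. Among its members were the thioesterase gene Acot1 (-1.69) and Ech1 (-1.19), while Ucp2 rose by 0.80. The 30 genes of pyruvate dehydrogenase control and the TCA cycle had a median of -0.41 (8 fell; 23 lower and 1 higher when adjusted over the list alone; camera, adjusted p = 2.04e-11). Under an estimated correlation, camera gave adjusted p = 0.234. The members included Suclg1 (-0.77) and Pdk1 (-0.49). The 37 nuclear-encoded genes of oxidative phosphorylation had a median of -0.38 (2 fell, 33 lower when adjusted over the list alone; camera, adjusted p = 1.88e-14). Camera's estimated correlation gave adjusted p = 0.238. A member that fell was Cox7a1 (-0.91).

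Triglyceride storage and lipolysis genes were lower as a set in CM KO (6 of 25 fell, 9 lower when adjusted over the list alone, median -0.24; camera, adjusted p = 5.37e-04). Camera with an estimated correlation gave adjusted p = 0.234. Among its members were the lipase gene Pnpla2 (-0.55), the lipid droplet gene Plin5 (-0.54) and Dgat2, of triglyceride synthesis (-0.60). In fatty acid uptake and trafficking, 3 of 21 fell (the transporter gene Slc27a1, -0.57, Cav1, of caveolae, -0.51, and Acsl1, -0.59) and the lipoprotein receptor gene Lrp1 rose by 1.04. In it 6 were lower and 1 higher when adjusted over the list alone. Camera called that list lower (median -0.31, adjusted p = 0.0105). With an estimated correlation, camera gave adjusted p = 0.226. The preset correlation gave an adjusted p of 0.0827 without Control replicate 2 and 0.0725 after quantile normalization. Glucose uptake and glycolysis genes went both ways, with 2 of 25 higher (Hk1, a hexokinase, 0.77, and Pfkp, 0.62) and 3 lower (Pfkfb1, -2.19, Slc2a12, -1.31, and Ldhb, -0.60), also 2 and 3 when adjusted over the list alone. The list was not called (median -0.05; camera, adjusted p = 0.841). Tbc1d4, which controls insulin-stimulated transport of GLUT4, fell from 2943 to 1118 (-1.38 ± 0.18; limma, adjusted p = 0.00303). It did not pass without Control replicate 1 (-1.06), and Pdk4 passed without Total KO replicate 1 (-1.17). Of the genes chosen in advance, Nppa and Myh7 passed. The others stood at -1.17 for Pdk4, 0.03 for Angptl4, -0.71 for Ucp3, -0.05 for Slc2a1, -0.22 for Slc2a4, -0.33 for Fabp3, -0.42 for Lpl, -0.20 for Plin2 and 0.54 for Nppb. Angptl4 was -0.03 without Control replicate 1 and -0.14 without CM KO replicate 3. Slc2a1 was 0.18 without Control replicate 2 and 0.02 without CM KO replicate 2, and Slc2a4 was 0.07 without Control replicate 2.

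**Figure D3:**
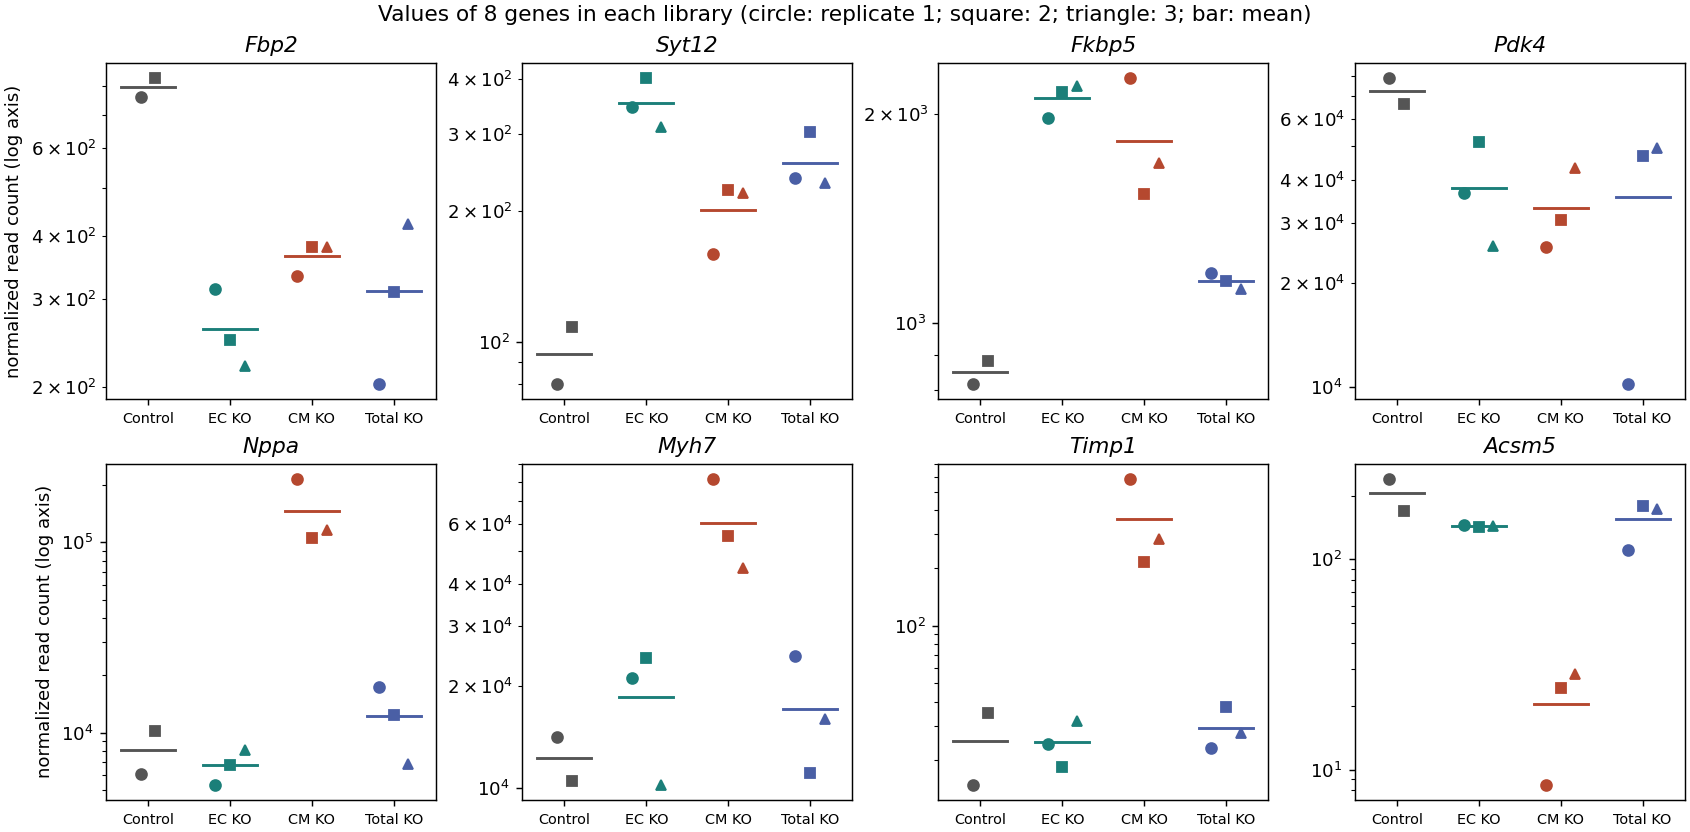
Normalized read counts (log axis) of Fbp2, Syt12, Fkbp5, Pdk4, Nppa, Myh7, Timp1 and Acsm5 in the 11 heart libraries by group; circles, squares and triangles mark replicates 1, 2 and 3 and bars are group means (n = 2 for Control, n = 3 for each knockout group). Fkbp5 averages 848 in Control, 2111 in EC KO and 1149 in Total KO, and Nppa averages 146172 in CM KO against 8115 in Control.

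In Total KO hearts, Tnfrsf19, of the tumor necrosis factor receptor family, fell from 172 ± 47.1 in Control to 44.2 ± 2.33 (log2 -1.91 ± 0.26; limma, adjusted p = 0.0137). Skeletal alpha-actin (Acta1) rose from 2997 ± 1103 to 17575 ± 10946 (2.43 ± 0.40; limma, adjusted p = 0.0497). Ankrd23, an ankyrin repeat protein of the sarcomere, rose from 5005 ± 1154 to 10384 ± 952 (1.07 ± 0.14; limma, adjusted p = 0.0117), and Cpxm2, of the carboxypeptidase family, from 759 ± 118 to 1581 ± 31.6 (1.07 ± 0.15, adjusted p = 0.0147). Syt12 rose to 257 ± 39.8 (1.44 ± 0.19; limma, adjusted p = 0.0137), and Sorcs2, a sorting receptor gene, fell from 329 ± 10.2 to 107 ± 18.2 (-1.62 ± 0.25, adjusted p = 0.0315). Tnfrsf19 did not pass without Control replicates 1 (-2.19) and 2 (-1.63) or each Total KO replicate in turn (-1.95 to -1.89). Acta1 lost its call without each library but CM KO replicate 1 and EC KO replicate 3 (1.96 to 2.82). Ankrd23 did not pass without Total KO replicates 1 (1.01) and 3 (1.05). Without Control replicate 1, Cpxm2 (0.91) and Syt12 (1.23) did not pass, nor did they without each Total KO replicate in turn (1.05 to 1.08 and 1.32 to 1.51). Sorcs2 passed only with the Control, EC KO and Total KO libraries all kept (-1.72 to -1.48 without one).

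In all, 11 genes passed between Total KO and Control, 8 higher and 3 lower (limma, adjusted p under 0.05; 1052 genes had an unadjusted p under 0.05). The other rises were Kcnc1 (1.91), Cnksr1 (1.30), Pdzd3 (1.39) and Nlrc3, of the NOD-like receptor family, from 11.4 ± 1.82 to 47.4 ± 8.07 (1.96; its level lay below that set for naming genes, and it was chosen after its values were seen). Cnksr1 did not pass without Control replicate 1 (1.41), nor Pdzd3 without either Control replicate or Total KO replicates 2 and 3 (1.29 to 1.49). Nlrc3 did not pass without Control replicate 1 or each Total KO replicate in turn (1.81 to 2.07), nor Kcnc1 without either Control replicate, each Total KO replicate in turn, EC KO replicate 2 or CM KO replicate 2 (1.77 to 2.01). The count was 1 without Control replicate 1, 22 without Control replicate 2, 33 without CM KO replicate 1, and 4, 4 and 3 without Total KO replicates 1, 2 and 3. Of the 10 named here that passed, 1 and 5 passed without Control replicates 1 and 2, and 2, 2 and 1 without Total KO replicates 1, 2 and 3. It was 8, 7 and 9 without EC KO replicates 1, 2 and 3, and 10, 8 and 9 without CM KO replicates 1, 2 and 3. The count of 11 was 7 with no filter, 100 by DESeq2, 72 with 3 doubted libraries left out and 26 after rescaling by library totals, of which 11 were higher and 15 lower (8 and 5 after quantile normalization).

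Camera called 6 of 32 gene lists between Total KO and Control, of which 5 are given here, and 0 with an estimated correlation. Fry called 0 of 32, and its mixed form called 2. PPAR target genes were lower as a set in Total KO than in Control (1 of 31 fell, and 4 were lower when adjusted over the list alone, median -0.26; camera, adjusted p = 9.31e-06). The estimated correlation gave adjusted p = 0.809 for camera. Acot2 stood at 1485 ± 342 against 2865 ± 67.1 (-0.98), passing without CM KO replicate 1, and Acot1 at -1.43. Beta-oxidation genes had a median of -0.12 over 25 members, with 0 passing by limma over all genes (3 at an unadjusted p under 0.05, 0 by edgeR and 0 by DESeq2) and 0 when adjusted over the list alone. Camera called them lower (adjusted p = 0.0190). Camera gave adjusted p = 0.860 with an estimated correlation. With the preset correlation the adjusted p was 0.210 without Control replicate 1 and 0.114 without Total KO replicate 2. Genes of glucose uptake and glycolysis were higher as a set (median 0.14 over 25; camera, adjusted p = 0.00300). Under an estimated correlation, camera gave adjusted p = 0.809. Of its genes, 0 passed by limma (9 at an unadjusted p under 0.05, 0 by edgeR and 2 by DESeq2), with 2 higher when adjusted over the list alone. At the preset correlation the adjusted p was 0.570 without Control replicate 1. Hk2, a hexokinase, stood at 5534 ± 1146 against 3094 ± 627 (0.83) and Pfkfb2 at 0.97. Integrated stress and unfolded protein response genes were higher as a set (median 0.11 over 25; camera, adjusted p = 0.0115). Camera's estimated correlation gave adjusted p = 0.809. By limma 0 of its genes passed (4 at an unadjusted p under 0.05, 0 by edgeR and 0 by DESeq2), with 4 higher when adjusted over the list alone. The preset correlation gave an adjusted p of 0.0520 without Control replicate 2, 0.241 without Total KO replicate 1, 0.0912 with a filter at a mean of 50 and 0.416 with 3 doubted libraries left out. Ddit3 stood at 0.56 and Atf4 at 0.38. Cell cycle genes were lower as a set (median -0.62 over 17; camera, adjusted p = 0.00800). Camera with an estimated correlation gave adjusted p = 0.809. Of its genes, 0 passed by limma (3 at an unadjusted p under 0.05, 0 by edgeR and 0 by DESeq2), with 0 when adjusted over the list alone. With the preset correlation the adjusted p was 0.134 without Control replicate 1 and 0.592 with a filter at a mean of 50. Top2a stood at -1.42 and Mki67 at -0.96.

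Of the genes chosen in advance, the log2 differences between Total KO and Control were -1.33 for Pdk4, -0.27 for Angptl4, -0.93 for Ucp3, 0.43 for Slc2a1, 0.41 for Slc2a4, 0.03 for Fabp3, 0.21 for Lpl, 0.04 for Plin2, 0.53 for Nppa, 0.36 for Nppb and 0.42 for Myh7, none of which passed limma's test. Pdk4 was -0.59, Ucp3 -0.28 and Angptl4 0.59 without Total KO replicate 1, whose Pdk4 value was 10175 against a group mean of 35484 ± 21951. Lpl was -0.04 without Control replicate 2. Fabp3 was -0.01 without Control replicate 1 and -0.02 without Total KO replicate 3, and Plin2 was -0.23 and -0.09 without Total KO replicates 2 and 3. The lists of fibrosis and extracellular matrix (median 0.03), macrophages (0.05) and cardiac stress (0.20) were not called in Total KO against Control (camera, adjusted p = 0.934, 0.877 and 0.0690).

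**Figure D4:**
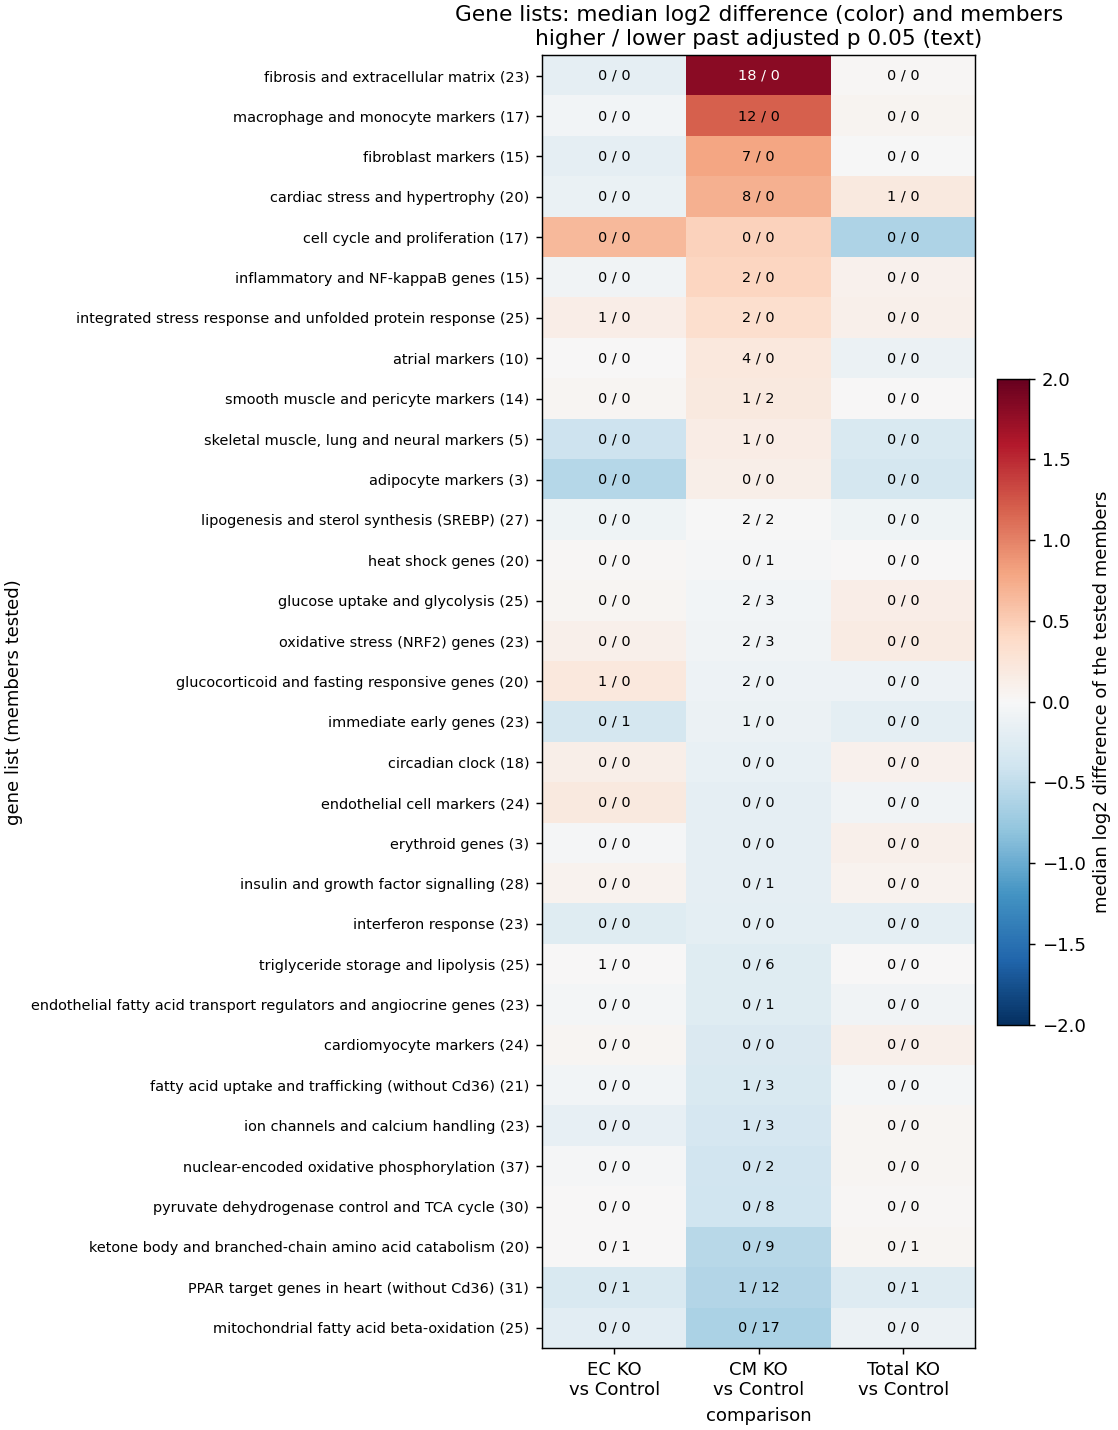
Median log2 difference from Control of the tested members of 32 gene lists in EC KO, CM KO and Total KO (color scale in log2), with the numbers of members higher and lower past adjusted p under 0.05 over all genes written in each cell. The fibrosis and extracellular matrix list stands at 1.80 in CM KO, -0.19 in EC KO and 0.03 in Total KO.

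Syt12, Cnksr1, Pdzd3 and Nlrc3 were higher in each of EC KO, CM KO and Total KO than in Control (limma, adjusted p under 0.05 in each comparison). EC KO and CM KO shared 6 higher and 8 lower genes, with 2 in opposite directions, against 0.724 and 0.457 for independent lists; the lower ones included Fbp2, Adra1b and Slc40a1. EC KO and Total KO shared 6 higher and 2 lower genes (0.0136 and 0.00439 for independent lists), among them Kcnc1, Ankrd23 and Tnfrsf19. CM KO and Total KO shared 5 higher genes, among them Acta1, and 1 lower gene (0.263 and 0.0721). Since the 3 comparisons used the same 2 Control libraries, which cannot be split, part of any excess may come from the shared controls. In 100 simulations with shared controls and no change, the means were 0, 0.01 and 0 shared genes. Those simulations hold no changed genes to be called, so they cannot show how many of the shared genes came from the controls. Across 12976 genes, which are not independent replicates, the log2 differences correlated with r = 0.06 for EC KO and CM KO, 0.51 for EC KO and Total KO and 0.23 for CM KO and Total KO, against 0.60 from shared controls alone in each pair. The covariance minus the simulated one was -0.0284, 0.0136 and -0.00748.

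In the direct comparison of EC KO and CM KO, Nppa stood at 6741 ± 1402 in EC KO and 146172 ± 60498 in CM KO (log2 -4.38 ± 0.34; limma, adjusted p = 8.46e-05). Gbp6, a guanylate-binding protein gene, stood at 870 ± 40.1 in EC KO and 171 ± 22.4 in CM KO (2.35 ± 0.21; limma, adjusted p = 1.17e-04).

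In this comparison 2479 genes passed, 1131 higher and 1348 lower in EC KO (limma, adjusted p under 0.05). The largest differences in favor of EC KO also included Selenbp2 (3.96), Lrrc52 (3.56), Rhd (3.25), the Wnt inhibitor gene Wif1 (3.09), Acsm5 (2.90), Tmem150c (2.67), Cdo1 (2.47) and the glycine methyltransferase gene Gnmt (2.41). Those in favor of CM KO included Mybphl (-4.75), Cilp (-4.58), Tnc (-4.50), Ltbp2 (-4.22), Postn (-4.02), Abhd1 (-3.79), the chemokine gene Ccl8 (-3.72) and Timp1 (-3.71). Without CM KO replicate 1, Cilp was -3.77, Ltbp2 -3.28, Postn -3.06, Tmem150c 2.02 and Wif1 2.38 (3.85 without CM KO replicate 3). Without EC KO replicate 1, Tnc was -3.34, Ccl8 -2.32 and Abhd1 -2.81, without EC KO replicate 2 Abhd1 was -4.54, and without EC KO replicate 3 Tnc was -5.16 and Ccl8 -4.56. The glucose transporter genes Slc2a1 (0.53 ± 0.13; limma, adjusted p = 0.0177) and Slc2a4 (0.56, adjusted p = 0.0153) and lipoprotein lipase (Lpl, 0.70, adjusted p = 0.0445) were higher and Myh7 (-1.75, adjusted p = 0.00497) and Nppb (-1.32, adjusted p = 0.00719) lower in EC KO. Slc2a1 did not pass without EC KO replicate 2 (0.49) or CM KO replicates 2 (0.46) and 3 (0.50), nor Slc2a4 without EC KO replicate 2 (0.52). Lpl kept its call without CM KO replicate 2 or either Control replicate and lost it without each of the other 8 libraries (0.48 to 0.81). The count was 1614 without EC KO replicate 2, 1455 without CM KO replicate 1 and 1288 with 3 doubted libraries left out. Rescaling by library totals gave 641 higher and 2085 lower genes and put the median of all genes at -0.12.

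Camera called 15 of 32 gene lists between EC KO and CM KO, of which 6 are given here, and 0 with an estimated correlation. Fry called 18 of 32. Fibrosis and extracellular matrix genes were lower in EC KO than in CM KO (22 of 23, and 23 when adjusted over the list alone, median -2.07; camera, adjusted p = 2.99e-13). With an estimated correlation, camera gave adjusted p = 0.238. Macrophage markers were lower too (15 of 17, and 15 when adjusted over the list alone, median -1.31; camera, adjusted p = 4.41e-10). The estimated correlation gave adjusted p = 0.238 for camera. Cardiac stress genes were also lower (11 of 20, with 15 lower and 2 higher when adjusted over the list alone, median -1.11; camera, adjusted p = 3.64e-05). Camera gave adjusted p = 0.238 with an estimated correlation. Genes of beta-oxidation were higher (15 of 25, and 21 when adjusted over the list alone, median 0.43; camera, adjusted p = 3.48e-08). Under an estimated correlation, camera gave adjusted p = 0.336. Those of oxidative phosphorylation were higher too (15 of 37, and 31 when adjusted over the list alone, median 0.35; camera, adjusted p = 5.22e-10). Camera's estimated correlation gave adjusted p = 0.351. Endothelial markers were higher in EC KO (13 of 24, and 14 when adjusted over the list alone, median 0.39; camera, adjusted p = 5.62e-06). Camera with an estimated correlation gave adjusted p = 0.238. The members included Pecam1 (4218 against 2967, 0.51) and the cadherin gene Cdh5 (0.42; not passing without EC KO replicate 2, 0.36).

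In the direct comparison of Total KO and CM KO, Mybphl, a myosin-binding protein gene, stood at 4.22 ± 3.39 in Total KO and 219 ± 51.6 in CM KO (log2 -5.63 ± 0.67, and -5.01 without Total KO replicate 2; limma, adjusted p = 7.38e-04), Nppa at 12159 ± 5273 and 146172 ± 60498 (-3.61 ± 0.34, adjusted p = 2.71e-04) and Timp1 at 29.3 ± 7.46 and 361 ± 196 (-3.47 ± 0.39, adjusted p = 6.19e-04). Acsm5, an acyl-CoA synthetase gene, stood at 155 ± 38.2 in Total KO and 20.6 ± 10.7 in CM KO (2.98 ± 0.35; limma, adjusted p = 7.32e-04), and Dct, dopachrome tautomerase, at 108 ± 29.5 and 23.2 ± 8.94 (2.20 ± 0.31, adjusted p = 0.00186).

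Here 2128 genes passed, 1064 higher and 1064 lower in Total KO (limma, adjusted p under 0.05). Values in favor of Total KO included Lrrc52 (3.36), Rhd (3.26), Tmem150c (3.06), Lgi1 (2.19), Gnmt (2.10), Nlrp10 (1.94) and Clcn1 (1.91). Those in favor of CM KO were Ltbp2 (-3.77), Comp (-3.77), Cilp (-3.49), Col8a2 (-3.29), Postn (-3.28), Angptl7 (-2.88) and Abhd1 (-2.80). Ltbp2 was -2.84, Comp -2.70, Cilp -2.68, Postn -2.32, Angptl7 -2.11, Tmem150c 2.41, Clcn1 1.18 and Nlrp10 1.13 without CM KO replicate 1, and Comp was -4.56, Col8a2 -3.93 and Angptl7 -3.57 without CM KO replicate 2. Slc2a1 (0.48; limma, adjusted p = 0.0293), Slc2a4 (0.64, adjusted p = 0.0106) and Fabp3 (0.36, adjusted p = 0.0471) were higher and Myh7 (-1.85, adjusted p = 0.00565) lower in Total KO. Of 23 named genes that passed, 6 lost the call without 1 library. Fabp3 lost it without each EC KO replicate (0.36), CM KO replicates 1 (0.27) and 3 (0.39) and Total KO replicates 2 (0.33) and 3 (0.31). Slc2a1 lost it without CM KO replicates 2 and 3 (0.41 and 0.46) and Total KO replicates 1 and 3 (0.47 and 0.42), and Abhd1 without CM KO replicates 1 and 3 (-2.85 and -2.56) and Total KO replicates 1 and 2 (-2.63 and -2.73). Lgi1 lost it without CM KO replicate 1 (1.49) and Total KO replicates 1 and 3, Clcn1 without Total KO replicates 1 and 3, and Nlrp10 without each Total KO replicate (1.89 to 1.97). Of 32 gene lists, camera called 18, of which 3 are given here, and 0 with an estimated correlation, while fry called 19. Fibrosis and extracellular matrix genes were lower (21 of 23, and 23 when adjusted over the list alone, median -1.91; camera, adjusted p = 1.47e-13). With an estimated correlation, camera gave adjusted p = 0.319. Macrophage markers were lower as well (15 of 17, and 16 when adjusted over the list alone, median -1.13; camera, adjusted p = 4.18e-11). The estimated correlation gave adjusted p = 0.319 for camera. Genes of beta-oxidation were higher (18 of 25, with 24 higher and 1 lower when adjusted over the list alone, median 0.54; camera, adjusted p = 9.87e-11). Camera gave adjusted p = 0.319 with an estimated correlation. The count of 2128 was 1054 without CM KO replicate 1, 1209, 1249 and 1036 without Total KO replicates 1, 2 and 3, 3553 with a weight per library and 917 with 3 doubted libraries left out. Rescaling by library totals gave 547 higher and 1744 lower genes and put the median of all genes at -0.14.

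Between Total KO and EC KO, 5 genes passed, all lower in Total KO (limma, adjusted p under 0.05; 1355 genes had an unadjusted p under 0.05). Fkbp5, the glucocorticoid-induced cochaperone, stood at 1149 ± 30.5 in Total KO and 2111 ± 119 in EC KO (log2 -0.88 ± 0.12; limma, adjusted p = 0.0270). Trp53inp1, a p53-inducible gene, stood at 234 ± 32.6 and 543 ± 122 (-1.19 ± 0.17; limma, adjusted p = 0.0270), the proteoglycan gene Spock2 at 336 ± 47.3 and 717 ± 47.6 (-1.10 ± 0.14, adjusted p = 0.0270), and Iqgap3, a scaffold gene of dividing cells, at 12.3 ± 1.95 and 64.9 ± 20.2 (-2.27 ± 0.31, adjusted p = 0.0270). Ckap2l, of the mitotic spindle, stood at 3.10 and 43.5 ± 10.7 (-3.44 ± 0.49; limma, adjusted p = 0.0300). The next genes by p, at an adjusted p of 0.0619 by limma, included Cdkn1a (1058 ± 365 and 3125 ± 304, -1.63), the pericyte gene Rgs5 (-0.55), the mitotic genes Nek2 (-2.57) and Hmmr (-2.81) and the clock gene Arntl (-1.39). These 5 genes passed without CM KO replicate 1, with the same differences. Of the 5 that passed, only Spock2 did so without either Control replicate, Iqgap3 (alone) without EC KO replicate 1, Spock2 and Trp53inp1 without EC KO replicate 3 or Total KO replicate 1, and 0 without EC KO replicate 2 or Total KO replicates 2 and 3. Fkbp5 ranged from -0.92 to -0.85.

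Cell cycle genes were lower as a set in Total KO than in EC KO (median -1.11 over 17; camera, adjusted p = 4.39e-13). Under an estimated correlation, camera gave adjusted p = 0.0730. By limma 0 of its genes passed over all genes (12 at an unadjusted p under 0.05, 0 by edgeR and 4 by DESeq2), with 11 lower when adjusted over the list alone. Mki67 stood at 40.0 ± 2.94 and 149 ± 48.7 (-1.83) and Top2a at -2.29, both passing without CM KO replicate 1. Endothelial markers were lower as a set (median -0.25 over 24; camera, adjusted p = 1.05e-07). Camera's estimated correlation gave adjusted p = 0.0714. Of its genes, 0 passed by limma (11 at an unadjusted p under 0.05, 0 by edgeR and 2 by DESeq2), with 10 lower when adjusted over the list alone. Pecam1 stood at -0.40, Cd93 at -0.45 and Cdh5 at -0.35. Glucocorticoid and fasting responsive genes were lower as a set (1 of 20, Fkbp5, and 3 when adjusted over the list alone, median -0.35; camera, adjusted p = 0.00108). Camera with an estimated correlation gave adjusted p = 0.0714. The count of 5 was 1 without either Control replicate, 1 without EC KO replicate 1, 0 without EC KO replicate 2, Total KO replicate 2 or Total KO replicate 3, and 28 without CM KO replicate 1. It was 0 with no filter on low values, 3 with a higher filter, 14 from these 2 groups alone, 116 with a weight per library, 4 by edgeR, 70 by DESeq2 and 17 with 3 doubted libraries left out.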

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

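The tests of the explanations for the matrix, glucocorticoid and PPAR patterns (1 library as the source, the share of cardiomyocytes, loss of Cd36 by itself and the hour of collection) were chosen only after the result was seen. The intervals of medians were also added after the values were seen, and with them the tests of EC KO replicate 1, of 1 Control library and of Total KO replicate 1, which had argued against those libraries, became undecided. These intervals run over the genes of a list, which are not independent replicates, and do not measure the spread between libraries. The test of the clock genes had been taken as support for a different hour of collection; as they were parted after the values were seen, it was later set to undecided.

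The knockout groups were compared directly, by the contrast between them, and genes passed in each of the 3 comparisons. The run of label numbers differs between these groups, and Cre transgene and mouse line may differ too. The counts therefore cannot be assigned to the deletions alone. EC KO and CM KO differed in 2479 genes, Total KO and CM KO in 2128 and Total KO and EC KO in 5 (limma, adjusted p under 0.05). In each comparison 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many genes; the highest of the other splits gave 0, 0 and 1. These splits are too few for a share under 0.05. For the 1853 genes that differed among the 4 groups, 1 of 100 regroupings, the real one, gave as many, and the highest of the others gave 1571. None of the other regroupings drawn reached the real count. Since the groups go in part with runs of label numbers, this does not tell genotype from those runs. The count of 2479 was 1614 without EC KO replicate 2 and 1455 without CM KO replicate 1. The count of 2128 was 1054 without CM KO replicate 1 and 1209, 1249 and 1036 without Total KO replicates 1, 2 and 3. The count of 5 was 1 without Control replicate 1, Control replicate 2 or EC KO replicate 1, 0 without EC KO replicate 2, Total KO replicate 2 or Total KO replicate 3, and 28 without CM KO replicate 1. The count of 1853 was 1016 without CM KO replicate 1, 940 without CM KO replicate 3 and 1142 without Total KO replicate 3.

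Matrix, fibroblast and macrophage genes stood higher in CM KO than in Control, with a median log2 difference of 1.28 over 55 genes. The camera calls of the 3 lists were lost with an estimated correlation (adjusted p = 0.226 in each). Fry, which tests each list by itself, called the matrix, fibroblast and macrophage lists higher (adjusted p = 0.0181, 0.0169 and 0.0169). Without CM KO replicate 1, the library farthest from the others, the median was 0.98 (95% interval over the 55 genes, 0.91 to 1.09). That remaining median argues against that library as the whole source. Endothelial markers had a median of -0.17 (5 of 24 above 0), lower than the 55 genes by 1.45 (pooled SD 0.83). This argues against a lower share of cardiomyocytes as the sole source, since that alone raises the markers of every other cell type alike. Cardiomyocyte markers had a median of -0.28 and were called lower (camera, adjusted p = 0.00241, and 0.542 with an estimated correlation). A lower share as a part of the pattern stays open. In Total KO the 55 genes had a median of 0.0332 against Control and -1.30 against CM KO (SD 0.86), which argues against loss of Cd36 from cardiomyocytes by itself, provided that the total deletion reached cardiomyocytes. The MHC-cre transgene, the mouse line, the run of label numbers, and a cardiomyocyte deletion with endothelial Cd36 left in place all go with the CM KO group, could not be separated and were not tested.

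Glucocorticoid and fasting responsive genes stood higher in EC KO than in Total KO, with a median of 0.35 over 20 genes, of which 1 passed. The camera call was lost with an estimated correlation (adjusted p = 0.0714), while fry, which tests the list by itself, called it (adjusted p = 0.00910). The clock genes that peak with Arntl had a median of 0.85 (4 of 4 higher in EC KO) and those that peak with Dbp a median of -0.42 (8 of 10 lower), with 1.27 between them. These 14 genes were picked after the values were seen, 4 of the 18 tested clock genes are on neither side, and by limma 0 of the 18 passed (8 at an unadjusted p under 0.05, 0 by edgeR and 3 by DESeq2). Adjusted over the list alone, 3 clock genes were higher and 3 lower in Total KO than in EC KO. The whole list was not called by camera (adjusted p = 0.561), which asks for a shift one way and cannot show 2 sides that move apart. It was also not called by the mixed form of fry (adjusted p = 0.0516). A different hour of collection stays open. Without EC KO replicate 1, the library of lowest depth, the median was 0.32 (95% interval over the 20 genes, 0.13 to 0.40). How much of 0.35 that library gave stays open. The hour of collection is not in the labels, and the deletions themselves, which differ between these groups, may also account for the pattern.

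PPAR target genes stood lower than in Control in EC KO (median -0.31) and Total KO (-0.26) over 31 genes, of which 1 passed in each. The camera calls were lost with an estimated correlation (adjusted p = 0.855 and 0.809) and with fry (0.360 and 0.668). Against 1 Control library alone, the medians were -0.33 and -0.28 in EC KO and -0.23 and -0.23 in Total KO, and the upper bound nearest to 0 was -0.07, so a part given by 1 Control library could not be excluded. Without Total KO replicate 1 the median in Total KO was -0.18 (95% interval over the 31 genes, -0.25 to -0.08). How much of -0.26 that library gave stays open. Against Control, the clock genes that peak with Arntl and those that peak with Dbp had medians of 0.58 and -0.45 in EC KO and of -0.37 and 0.09 in Total KO. By limma 0 of 18 clock genes passed in each (8 and 7 at an unadjusted p under 0.05, 0 by edgeR and 0 by DESeq2), which leaves a different hour of collection open. A difference in feeding was not tested, and the deletion of Cd36 stays among the open explanations.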

How the results depend on the processing

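The omission of EC KO, CM KO and Total KO replicates 1 together was chosen only after the values were seen; all other settings were planned. Across the 67 list calls, 1590 of 1742 results under other settings kept direction and call, 152 lost the call and 0 turned direction. Their adjusted p (camera on values of limma, edgeR or DESeq2, or fry) ranged from 9.19e-27 to 0.916. The highest of each call lay between 0.0714 and 0.916. Of 5323 results for 223 gene differences named in the text, 4633 kept direction and side of the threshold, 607 lost and 58 gained a call, and 25 turned sign. edgeR shared 40 of the 41 genes called in EC KO against Control, 737 of 739 in CM KO, 10 of 11 in Total KO, 2283 of 2479, 4 of 5 and 2112 of 2128; DESeq2 shared 41, 737, 11, 2267, 5 and 2103. The median of all genes moved by over 0.1 under rescaling by library totals alone, to -0.12 in EC KO against CM KO and to -0.14 in Total KO against CM KO. At the depth of EC KO replicate 1 (2268403 reads), genes of low level are counted with few reads.

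The 41 genes of EC KO against Control were 22 with no filter, 27 with a weight per library, 162 by DESeq2 and 64 without the 3 libraries (5 without Control replicate 2, 12 without EC KO replicate 1, 7 without EC KO replicate 2, 27 and 22 without CM KO replicates 2 and 3, 26 and 25 without Total KO replicates 2 and 3, and 84 without CM KO replicate 1). The 739 of CM KO against Control were 61 from these 2 groups alone and 1276 by DESeq2 (26 without Control replicate 1, 366 without CM KO replicate 1, 476 without Total KO replicate 3 and up to 999). The 11 of Total KO against Control were 7 with no filter, 26 with library totals, 100 by DESeq2 and 72 without the 3 libraries (1 and 22 without Control replicates 1 and 2, 4, 4 and 3 without Total KO replicates 1, 2 and 3, and 33 without CM KO replicate 1). The 2479 of EC KO against CM KO were 1288 without the 3 libraries (1455 without CM KO replicate 1, 1614 without EC KO replicate 2, and up to 2582). The 5 of Total KO against EC KO were 0 with no filter (4 by edgeR), 3 with a filter at 50, 14 from these 2 groups alone, 116 with weights, 70 by DESeq2 and 17 without the 3 libraries (0 without EC KO replicate 2 or Total KO replicates 2 and 3, 1 without either Control replicate or EC KO replicate 1, and 28 without CM KO replicate 1). The 2128 of Total KO against CM KO were 3553 with weights and 917 without the 3 libraries (1054 without CM KO replicate 1, 1209, 1249 and 1036 without Total KO replicates 1, 2 and 3, and up to 2272). The 1853 among 4 groups were 3279 with weights and 977 without the 3 libraries (1016 and 940 without CM KO replicates 1 and 3, 1142 without Total KO replicate 3, and up to 2084). Fewer libraries leave fewer degrees of freedom. Leaving out either Control library costs the same degrees of freedom, so these do not explain why the 2 omissions gave unlike counts in Total KO against Control. Beyond that the cause was not tested.

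Cd36 in CM KO against Control (-1.03) no longer passed from these 2 groups alone (-1.03) or without Control replicate 1 (-0.87; range -1.20 to -0.87). In Total KO (-0.91) it passed with quantile normalization (-1.02), library totals (-0.96), weights (-0.89), DESeq2 (-0.92), without the 3 libraries (-0.83) and without CM KO replicate 1 (-0.91; range -1.08 to -0.75). In EC KO against CM KO (0.52) it no longer passed with no filter (0.52), quantile normalization (0.29), library totals (0.40), 2 groups alone (0.52), without the 3 libraries (0.32), EC KO replicate 1 (0.46), EC KO replicate 2 (0.53) or CM KO replicate 1 (0.38; range 0.38 to 0.60). In Total KO against CM KO (0.12) its sign turned with quantile normalization (-0.15), library totals (-0.0159) and without CM KO replicate 1 (-0.0259; range -0.03 to 0.20). The ranges were -0.67 to -0.34 in EC KO against Control and -0.48 to -0.32 in Total KO against EC KO. The causes were not tested.

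The number of lists called was 0 with an estimated correlation in each comparison. It was 0 by fry in EC KO (7 by camera) and Total KO (6) against Control, 3 with a filter at 50 in Total KO against Control, and 5 without the 3 libraries in Total KO against EC KO (3). With a library left out it ranged from 6 to 9 in EC KO, 16 to 21 in CM KO and 5 to 8 in Total KO against Control, 15 to 20 in EC KO against CM KO, 3 to 5 in Total KO against EC KO (5 without Total KO replicate 2) and 17 to 20 in Total KO against CM KO. By fry, 18 lists were called in CM KO against Control, 18 in EC KO against CM KO, 19 in Total KO against CM KO and 3 in Total KO against EC KO. The mixed form of fry called 9, 26 and 2 lists in EC KO, CM KO and Total KO against Control. It called 29 in EC KO against CM KO, 8 in Total KO against EC KO and 28 in Total KO against CM KO. Fry tests each list by itself, not against other genes.

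Signs that turned were of differences that had not passed; the causes were not tested. In EC KO against Control, Nppa (-0.24) was 0.14 without Control replicate 2 (from -0.62). In CM KO against Control, Angptl4 (0.03) was -0.0309 without Control replicate 1 and -0.14 without CM KO replicate 3 (up to 0.20), Slc2a1 (-0.05) was 0.0341 with library totals and 0.18 and 0.0175 without Control replicate 2 and CM KO replicate 2 (from -0.28). Slc2a4 (-0.22) was 0.0688 without Control replicate 2 (from -0.52), and Myl4 (-0.04) was 0.0428 with library totals and 0.42 and 0.00430 without Control replicate 1 and CM KO replicate 2 (from -0.51). In Total KO against Control, Angptl4 (-0.27) was 0.0604 with weights, 0.12 by edgeR, 0.12 by DESeq2 and 0.59 without the 3 libraries or Total KO replicate 1 (from -0.70). Fabp3 (0.03) was -0.10 with quantile normalization, -0.0248 with library totals and -0.00718, -0.00186 and -0.0207 without Control replicate 1 and Total KO replicates 2 and 3 (up to 0.11), Lpl (0.21) was -0.0361 without Control replicate 2 (up to 0.46), and Plin2 (0.04) was -0.00465 with quantile normalization, -0.0119 with library totals and -0.23 and -0.0944 without Total KO replicates 2 and 3 (up to 0.44).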

Other observations

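The test of the neighbours of Cd36 was set before the result was seen; the test of long genes was chosen only after the result was seen. In CM KO against Control, genes of ketone body and branched-chain amino acid catabolism were lower as a set (9 of 20 fell, 15 lower when adjusted over the list alone; median -0.55; camera on limma values, adjusted p = 7.00e-11; adjusted p = 0.226 with an estimated correlation). Dbt, a subunit of the branched-chain ketoacid dehydrogenase, fell from 1719 to 1009 (-0.79). Among ion channel and calcium handling genes, the potassium channel genes Kcnd2 (421 to 213), Kcnv2 (-1.92) and Kcnj3 (-0.70) fell and Kcnq1 rose (0.99), 3 lower and 1 higher also when adjusted over the list alone; the list was not called (median -0.33 over 23; camera, adjusted p = 0.0682). Oxidative stress genes went both ways: Gpx3 (1.32) and Gpx1 (0.60), glutathione peroxidases, rose, and Gsta4 (-0.99), catalase (Cat, -0.54) and superoxide dismutase (Sod2, -0.57) fell, with 4 higher and 7 lower of 23 when adjusted over the list alone (median -0.08; camera, adjusted p = 0.196). Genes of the integrated stress and unfolded protein responses were higher as a set (2 of 25 rose, Ddit3, 0.69, and Mthfd2, 1.73; also 2 when adjusted over the list alone; median 0.34; camera, adjusted p = 9.70e-04; adjusted p = 0.226 with an estimated correlation).

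Dmd, which encodes dystrophin and was chosen outside the naming rule after its values were seen, stood at 754 ± 144 (n = 3) in CM KO against 1880 ± 329 (n = 2) in Control (-1.32 ± 0.16; limma, adjusted p = 0.00181), 2153 ± 240 in EC KO and 2131 ± 180 in Total KO. It spans 2257 kb, and the hypothesis was that Cre recombinase acted on DNA sites other than loxP, more of which lie in long genes. Among the genes that passed in CM KO against Control and had a known span (700, 94.7%), 19 of 38 that span at least 200 kb were lower (50%), against 271 of 662 shorter ones (40.9%; Fisher's exact test, one-sided, p = 0.175). The test leaves the hypothesis undecided, and the labels give no group with Cre and intact Cd36.

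A second hypothesis was that DNA of another strain beside the targeted Cd36 gene changed its neighbours. Of 68 tested genes within 10 Mb of Cd36, 4 passed in CM KO against Control (3.91 for chance), 14 in EC KO against CM KO (13.1) and 13 in Total KO against CM KO (11.2), and the lowest adjusted p over the 6 comparisons was 1 (Fisher's exact test, one-sided). None of the comparisons with CM KO held over 2 times the number for chance. In them this argues against such DNA as a source of many calls near the gene, provided that the 2 groups compared differ in it. The labels do not state whether they do, and groups with the same DNA beside Cd36 could not show its effect. A few changed neighbours would also not stand out from the numbers for chance. In EC KO against Control, Total KO against Control and Total KO against EC KO, 0 of the 68 genes passed. Chance gave 0.223, 0.0614 and 0.0279 there, too few for the test to decide, so such DNA stays open in those comparisons. Positions were found for 93.9% of the tested genes.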
